A study of Mus musculus with 22 samples.

How the data were processed

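Copy number was measured in genomic DNA of thymocytes from 22 mice lacking Atm, the kinase that signals DNA double-strand breaks. Each mouse has 1 array of the Agilent mouse genome CGH design, on which its DNA, labelled with Cy5, competed with DNA of wildtype thymocytes, labelled with Cy3. Per the labels, 8 mice carried a thymic lymphoma and 14 showed no tumour to the naked eye. The labels give no strain, age or sex and do not state which part of Atm was altered. Per the labels' protocols, DNA was purified on a caesium chloride gradient, cut with AluI and RsaI and labelled with the Klenow enzyme. All arrays have 1 dye orientation, so dye and genotype cannot be separated.

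The deposited scanner files hold spot brightness as intensity for both channels, and the processed signals in them are background-subtracted and dye-normalised, per the file headers, by Feature Extraction 9.1.3.1 with protocol CGH-v4_91. The submitters' processing notes name Feature Extraction 9.1. The deposited log ratio of each spot is log10 of the red over the green processed signal, per the file headers. The 99th percentile of the difference from the ratio of the processed signals was 0.0651 in no-lymphoma mouse 11. It was 0 in every other array. The value table of the series was set against each array's scanner values and equalled the deposited log10 ratio with a largest difference of 0, so its scale, centring and direction are known (log10, no further centring, red over green). Its column medians were 0.00026, -0.00363, -0.0199, 0.000784, -0.00277, 0.00646, -0.00421 and -0.00245 for lymphoma mice 1 to 8. They were 0, -0.00426, 0.00717, 0.0144, 0, 0.000189, 0.00726, 0.0004, 0.0105, -0.00572, -0.00485, -0.00505, -0.00255 and 0.0164 for the arrays labelled no-lymphoma mouse 1 to 14. The build of the probe coordinates is not given in the sources used here, and all coordinates are those of the array files.

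Log2 ratios were computed from the processed intensity of red over green at the 238202 spots that are not controls. Spots with a feature or population outlier flag in either channel (3 to 111 per array) were left out, spots of a probe were averaged, and each array was centred on the median of its autosomal probes, with no loess and no quantile step. Of 235402 probes, 232626 carry a position, 220065 of them on autosomes, with a median spacing of 7850 bp. Median spot signals before background subtraction ran from 146 to 226 in green and from 146 to 397 in red, with local backgrounds of 41.0 to 89.0 and 50.0 to 82.0. Between 0.089% and 1.54% of spots per array were not well above background in at least 1 channel.

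Gene names are those of the array files, updated through a RefSeq table of the assembly GRCm38.p6 that was used for names only. Of 25705 names, 12155 matched a symbol, 3590 a synonym and 1 an accession, while 9959 stayed as in the files. Left out were 100 genes whose probes lay on more than 1 chromosome or spanned over 3 Mb. A gene's value is the mean of its probes, which left 24618 autosomal genes, 12986 of them with at least 3 probes.

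Each array was segmented by optimal partitioning (least squares, penalty of 3 times the log of the probe number times the noise variance per break, at least 5 probes per segment), written in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. Noise is the spread of differences between neighbouring probes. A probe over 4 noise SD from the running 7-probe median was set to that limit. A segment mean of 0.25 or more was called a gain and one of -0.25 or less a loss, and a chromosome median beyond 0.15 a gained or lost chromosome. Sex chromosomes, segments lying mostly in an antigen receptor locus and segments called in the same direction in 11 or more of the 22 arrays were left out of the altered Mb and the segment number, but not of the calls per gene. Where arrays were left out, the limit for shared segments fell with the number of arrays. Receptor loci were bounded by flanking genes, with 1 Mb on each side as a comparison.

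Values per mouse were compared with an exact two-sided permutation test of the difference of means over all 319770 splits of the arrays, and Benjamini-Hochberg adjustment within each family (19 autosomes, 5 loci or 6 gene lists). Gene means were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, adjusted p under 0.05), between the groups and, with a mean beyond 0.25 in size, against 0. The wildtype DNA is the reference channel, so tests against 0 leave out its own spread. Calls over each gene's midpoint were tested with a two-sided Fisher exact test (scipy 1.17.1), adjusted over gains and losses together. Each array is 1 mouse, and the number of arrays limits the precision.

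Scan batches were read from the file headers. Batch 1 held lymphoma mice 1, 3 and 4 and no-lymphoma mouse 2, and batch 2 only the arrays labelled no-lymphoma mouse 1, 3 and 4. Batch 3 held lymphoma mice 2 and 5 and no-lymphoma mice 5 and 6, and batch 4 only no-lymphoma mice 8, 9, 10 and 12. Batch 5 held lymphoma mouse 8 and no-lymphoma mice 7, 11 and 14, and batch 6 lymphoma mice 6 and 7 and no-lymphoma mouse 13. Values with batch as a block use the 4 batches that hold both groups (permutation within batches, 288 arrangements), except in limma. There batch is a fixed term between the groups and, against 0, a random block with a consensus correlation of 0.122. In batches of 3 or 4 arrays no permutation or Fisher p can fall below 0.05, so within-batch differences are given as values.

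Groups, tests, gene lists (tumour suppressors, oncogenes, break repair, Notch pathway, T-cell identity, and gene families that vary between strains) and the naming rule were fixed before the data were examined. Named are Atm, list genes called in at least 2 lymphoma mice or passing a test (at most 25), the 10 highest and 10 lowest differences, the 10 smallest Fisher p in each direction, and the 10 highest and 10 lowest means off 0 per group, at most 1 per 1 Mb window, with up to 10 gain and 10 loss regions shared by at least 3 lymphoma mice. Names that are only accessions in the files are not printed. Of the strain-variable families, only members that passed a test are named. A list gene that the naming rule takes is not reported here, by itself or among outlying values, and still counts in its list.

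Alternatives were call thresholds of 0.15 and 0.4, at least 10 probes per segment, a penalty factor of 6, shared segments and receptor loci kept in, removal of a loess on the GC content of the probe and of 101 neighbouring probes, limma normexp with an offset of 50, the value table, only probes well above background on every array, centring on the mode, medians of probes, genes with at least 1 probe, limma array weights, scan batch as a block, and the noisiest array of each group left out. Normexp used median spot signals in place of the planned means, since mean signals are present in the files of 4 arrays only. After the data were seen, the sign was turned or the arrays left out for scan batch 2, the sign was turned for the arrays labelled no-lymphoma mouse 3, 4 and 9, the 5 arrays with a low Atm probe were left out, and batch was added as a block to the remaining results. The scripts were tested on simulated data. Of 200 genes shifted among 12986, limma recovered 48.5% at a shift of 0.25 and 91% at 0.5 log2. The segmentation made no false call, and at the median noise it found every 10-probe segment at a shift of 1.0, while at the noise of the noisiest array it found none of these. The simulated noise was independent between probes, so the lack of false calls does not cover noise shared by neighbouring probes.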

Results

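Thymocyte DNA of 22 Atm-deficient mice was compared by array CGH with wildtype thymocyte DNA, to find how the DNA of 8 mice with a thymic lymphoma differed from that of 14 mice without a visible tumour. Values are log2 ratios of Atm-deficient over wildtype DNA, given as mean ± SD with n = 8 for lymphoma and n = 14 for no lymphoma, and differences are lymphoma minus no lymphoma. Noise per array ranged from 0.15 to 0.37 in the lymphoma group and from 0.13 to 0.55 in the other. Over autosomal probes the 231 pairs of arrays correlated with a median r of 0.16, and no pair held equal values. In 8 pairs r lay under -0.3. It was -0.44, -0.48 and -0.41 for lymphoma mouse 3 with the arrays labelled no-lymphoma mouse 3, 4 and 9. It was -0.36, -0.42 and -0.40 for no-lymphoma mouse 12 with the same arrays, and -0.34 and -0.32 for the array labelled no-lymphoma mouse 4 with mice 11 and 14. The arrays labelled no-lymphoma mouse 3, 4 and 9 correlated at 0.82 to 0.87 with each other and were the noisiest. Of all pairs 4 lay over 0.8, the last being no-lymphoma mice 7 and 14 of scan batch 5 at 0.82. The labels state the dyes of every array, so the labelled direction was kept. Values with the sign turned for these 3 arrays, picked for their correlations, are given beside the labelled ones.

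Atm was the targeted gene, and 1 of its 12 probes (chromosome 9, 53461029 to 53461088) stood apart. This probe read 1.17 ± 0.14 in lymphoma mice, above 0.5 in 8 of 8, and 0.55 ± 0.83 in the others, above 0.5 in 9 of 14. The probe differed by 0.62 (exact permutation p = 0.0447), by 0.44 with scan batch as a block (exact permutation p = 0.0313), and by 0.08, 0.996, 0.39 and 0.06 within batches 1, 3, 5 and 6. It went the other way in the 3 arrays of scan batch 2, at -1.08, -0.72 and -0.63 for the arrays labelled no-lymphoma mouse 1, 3 and 4, and was low at 0.44 and 0.08 in those labelled no-lymphoma mouse 5 and 6. The mean of all Atm probes was 0.19 ± 0.06 against 0.05 ± 0.14, a difference of 0.13 (exact permutation p = 0.0132), and the 1 Mb on either side of the gene read -0.02 ± 0.02 and -0.04 ± 0.09. The labels do not give the altered part of Atm, so the other probes check no label. With scan batch as a block the difference was 0.08 (exact permutation p = 0.146), and within batches 1, 3, 5 and 6 it was 0.02, 0.14, 0.09 and 0.04. With the 5 arrays of a low probe left out it was 0.07 (exact permutation p = 0.0719). Turning the sign gave 0.07 for scan batch 2 and 0.11 for the arrays labelled no-lymphoma mouse 3, 4 and 9. Every direction below that uses the no-lymphoma group rests in part on the 3 arrays whose Atm probe goes against the others.

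**Figure D1:**
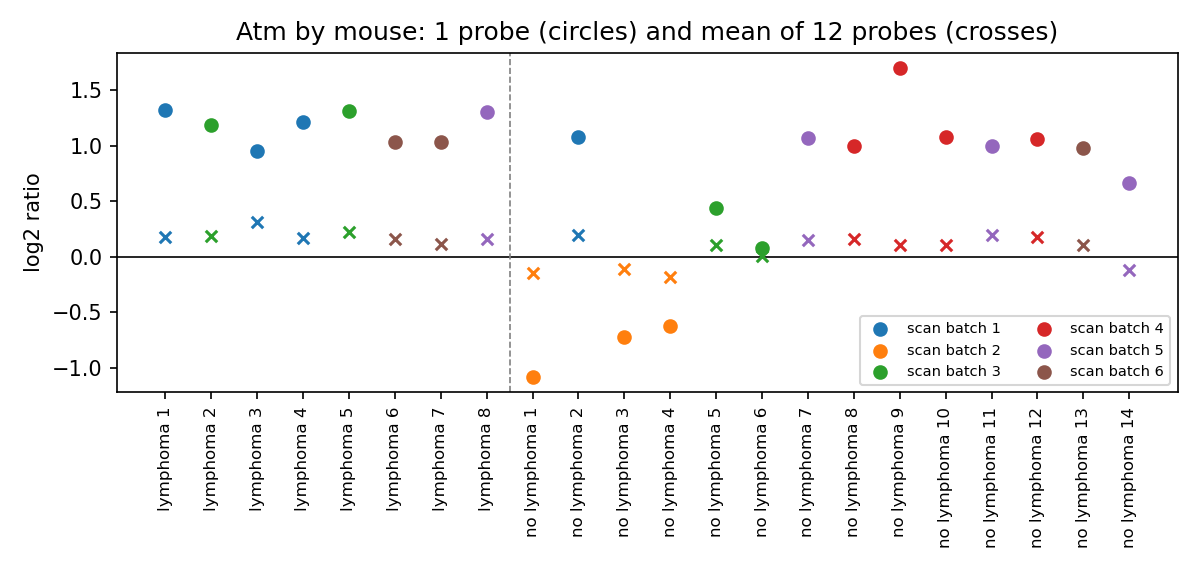
Log2 ratio at Atm for each of the 22 mice on the x axis, with circles for the probe at 53461029 and crosses for the mean of the 12 Atm probes, coloured by scan batch. The 3 circles below 0 are the arrays of scan batch 2, at -1.08, -0.72 and -0.63.

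Changes on chromosomes 12, 14 and 15 recurred in most of the 8 lymphomas. On chromosome 12 the distal end was lost, with a common core from 115312874 to 117798928 that holds Dnah11, an axonemal dynein, Rapgef5, a Ras-family exchange factor, and Sp4, a transcription factor. This core was called in 8 lymphoma mice and in no-lymphoma mice 2 and 11, at -0.87 ± 0.20 against -0.10 ± 0.26. A second loss on that chromosome, from 106743167 to 107786690 over the imprinted genes Meg3, Rtl1 and Dlk1, was called in 7 lymphoma mice and in no-lymphoma mice 11 and 14 (-0.81 ± 0.25 against -0.07 ± 0.30). On chromosome 14 a gain from 34677537 to 36920712 over Nrg3, a neuregulin growth factor, was called in 7 lymphoma mice and no other (1.02 ± 0.75 against -0.03 ± 0.11). On chromosome 15 a gain from 50565522 to 80076372, a stretch with the oncogene Myc, Trappc9 and Samd12, was called in 7 lymphoma mice and no-lymphoma mouse 11 (0.50 ± 0.14 against 0.08 ± 0.15).

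Further regions recurred in fewer tumours. Distal chromosome 1 from 168877001 to 180923868, which holds Ncstn, a subunit of the gamma-secretase that cuts Notch receptors, was gained in lymphoma mice 3, 4, 5, 6 and 8 and in no-lymphoma mice 2 and 11 (0.32 ± 0.27 against 0.09 ± 0.25). A 15-probe core on chromosome 2 from 26400799 to 26473212 over Notch1, a receptor that drives T-cell fate, Pmpca and Sec16a was gained in lymphoma mice 1, 2, 3 and 4 and in no-lymphoma mouse 11 (0.78 ± 0.83 against -0.01 ± 0.15). The T-cell kinase gene Lck lay in a gain on chromosome 4 from 128918449 to 129116222 in 3 lymphoma mice and no-lymphoma mouse 11, and Pop4 in one on chromosome 7 from 35157686 to 35259523 in 4 lymphoma mice and no-lymphoma mouse 2. Zfp619 lay in a gain from 35746365 to 35800447 on the same chromosome in 3 lymphoma mice and no-lymphoma mouse 2. The last gain core was 1 probe on chromosome 4. Losses on chromosome 14 beyond the T-cell receptor alpha locus, from 49068840 to 57109541 over Atp8a2, Mipep and Olfr49 and from 84900299 to 93425618 over Dach1 and Klhl1, were called in 4 lymphoma mice each, with 3 and 4 no-lymphoma mice. In all, 8 gain and 18 loss regions were called in at least 3 lymphoma mice, outside receptor loci and segments shared by 11 or more arrays. Further losses shared by 3 lymphoma mice lay on chromosome 14, such as 102517728 to 105362808 with Slitrk6, and on chromosome 7, 35073245 to 35094881 with 1600014C10Rik, also called in 4 and 3 no-lymphoma mice. The chromosome 7 loss, at -1.02 ± 1.62 against 0.30 ± 1.78, lies close to the chromosome 7 gains. The gain over Pop4 stood at 0.39 ± 0.61 against -0.15 ± 0.65. Values there spread widely in both groups, so the chromosome 7 calls do not show changes that arose in the tumours. The gain on chromosome 14 before the T-cell receptor alpha locus was called in 11 arrays, so it counts as shared and is given with its genes.

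In called segments lymphoma mice carried 263.1 ± 77.4 Mb of altered autosomal DNA and the others 78.1 ± 112 Mb, a difference of 185.0 Mb (exact two-sided permutation p = 0.000869). Values ran from 143 to 405 Mb in lymphoma mice and from 0.0954 to 387 Mb in the others, where 387, 215, 134, 134 and 106 Mb were found in the arrays labelled no-lymphoma mouse 11, 2, 14, 1 and 9. The lowest, 0.0954 and 0.253 Mb, came from the arrays labelled no-lymphoma mouse 4 and 3. Their noise was 0.49 and 0.55, and at 0.55 no simulated 10-probe segment was found. No-lymphoma mice 10 and 8, at 0.436 and 0.475 Mb, had low noise of 0.135 and 0.134. Gains differed by 132 Mb (p = 0.00116, same exact test) and losses by 53.2 Mb (p = 0.0255, same exact test). The number of segments was 79.3 ± 34.3 against 31.1 ± 42.4, a difference of 48.2 (exact permutation p = 0.0128). Blocked by scan batch the altered DNA differed by 154 Mb (exact permutation p = 0.0417), and within batches 1, 3, 5 and 6 by 78.4, 268, 39.1 and 199 Mb. The segment number differed by 19.2 with the block (exact permutation p = 0.465), and within these batches by -86.7, 105, -8.33 and 41.5, so it did not hold within batches. After the sign was turned, altered DNA differed by 181 Mb for scan batch 2 and 191 Mb for the arrays labelled no-lymphoma mouse 3, 4 and 9. The loss difference ended with the sign of scan batch 2 turned (40.7 Mb, exact permutation p = 0.104), with that batch left out (40.6 Mb, exact permutation p = 0.127) and with the 5 arrays of a low Atm probe left out (34.0 Mb, exact permutation p = 0.254). The distal chromosome 12 loss, called in 8 lymphoma and 2 no-lymphoma mice, lay near the limit for shared segments. It could be left out as shared when fewer arrays lowered that limit. Turning the array labelled no-lymphoma mouse 1, at 0.49 there, could do the same. The ended loss difference thus does not show that the losses rest on those arrays. The segment difference ended with scan batch 2 left out (39.8, exact permutation p = 0.0535) and with the 5 arrays left out (32.8, exact permutation p = 0.130).

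**Figure D2:**
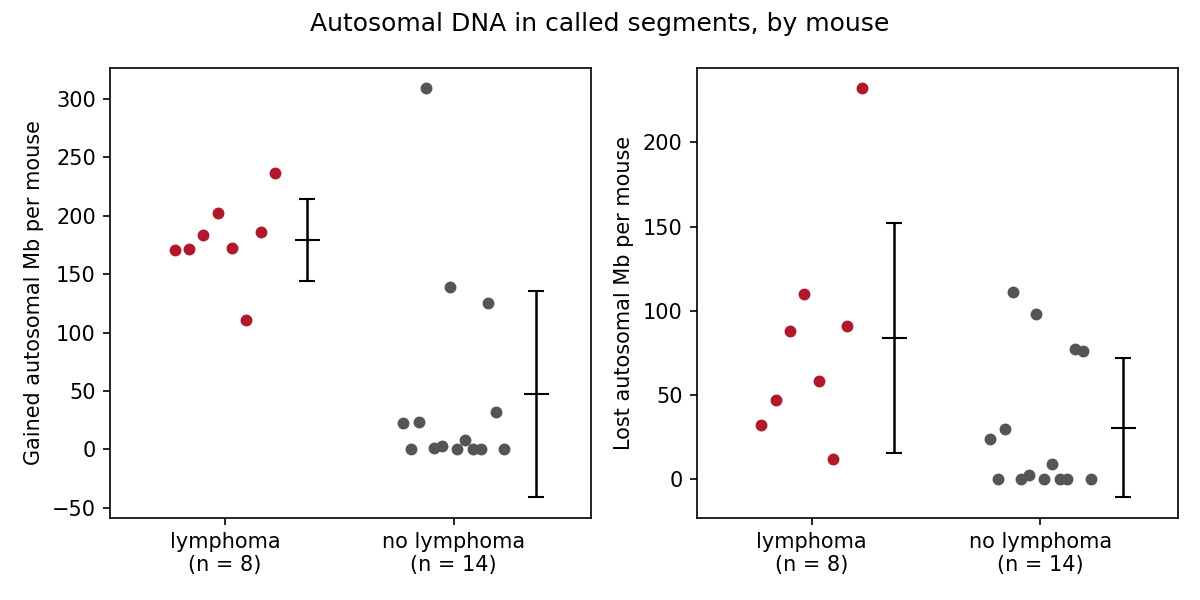
Gained (left) and lost (right) autosomal Mb in called segments on the y axis, with a point for each mouse of the 8 with and 14 without lymphoma; the bar beside each group is the mean ± SD. Total altered DNA ran from 143 to 405 Mb in lymphoma mice, and no-lymphoma mouse 11, the highest of the other group, had 387 Mb.

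Chromosome 15 was the only chromosome counted as gained in every lymphoma mouse. Its median was 0.46 ± 0.13 in lymphoma mice, 1.38 times the wildtype level, and 0.07 ± 0.14 in the others, a difference of 0.39 (exact permutation p = 3.75e-05, adjusted p = 0.000713). It counted as gained in 8 of 8 lymphoma mice and in 3 of 14 others. Those 3 were no-lymphoma mice 7, 11 and 14, at 0.17, 0.47 and 0.21. Chromosome 11 was higher by 0.04 (adjusted permutation p = 0.00171), while chromosomes 3, 6, 12, 13 and 18 were lower, by -0.03, -0.03, -0.09, -0.03 and -0.04 (adjusted permutation p = 0.00772, 0.00171, 0.0105, 0.0123 and 0.00171). No mouse crossed the calling threshold on chromosomes 3, 6, 11, 13 or 18. Chromosome 4 counted as gained in lymphoma mouse 2 and no-lymphoma mouse 11, with no difference between groups (0.03, adjusted permutation p = 0.63). Chromosome 14 counted as gained in 1 and lost in 2 mice of each group. Chromosome 12 counted as lost in 1 lymphoma and gained in 1 no-lymphoma mouse, and chromosome 1 as gained in 1 no-lymphoma mouse.

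These small shifts depended on how an array was centred. Centred on the mode, only chromosomes 15 and 11 passed, and chromosomes 6 and 13 turned to differences of 0.00086 and 0.000387. No chromosome passed after adjustment with scan batch as a block, where the smallest p that 288 arrangements allow, 0.00347, adjusts to 0.066 for a chromosome on its own. Chromosome 15 differed by 0.35 (exact permutation p = 0.0139, adjusted p = 0.066), and within batches 1, 3, 5 and 6 by 0.53, 0.49, -0.13 and 0.47. In batch 5 the direction was thus the opposite, with lymphoma mouse 8 at 0.15 against no-lymphoma mice 7, 11 and 14. Chromosome 11 differed by 0.03 with the block and 0.04, 0.04, 0.01 and 0.03 within these batches, and chromosome 12 by -0.13 and -0.33, -0.08, -0.06 and -0.06 (adjusted permutation p = 0.066 for both). Chromosomes 3, 6, 13 and 18 differed by -0.03, -0.03, -0.02 and -0.03 with the block (adjusted permutation p = 0.132, 0.066, 0.396 and 0.066). Within batches 1, 3, 5 and 6 chromosome 3 differed by -0.01, -0.03, -0.05 and -0.03, chromosome 6 by -0.02, -0.03, -0.03 and -0.03, chromosome 13 by -0.01, -0.02, -0.03 and -0.02, and chromosome 18 by -0.03, -0.04, -0.02 and -0.02. For the turned sign, chromosome 15 differed by 0.38 for scan batch 2 and 0.41 for the arrays labelled no-lymphoma mouse 3, 4 and 9.

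**Figure D3:**
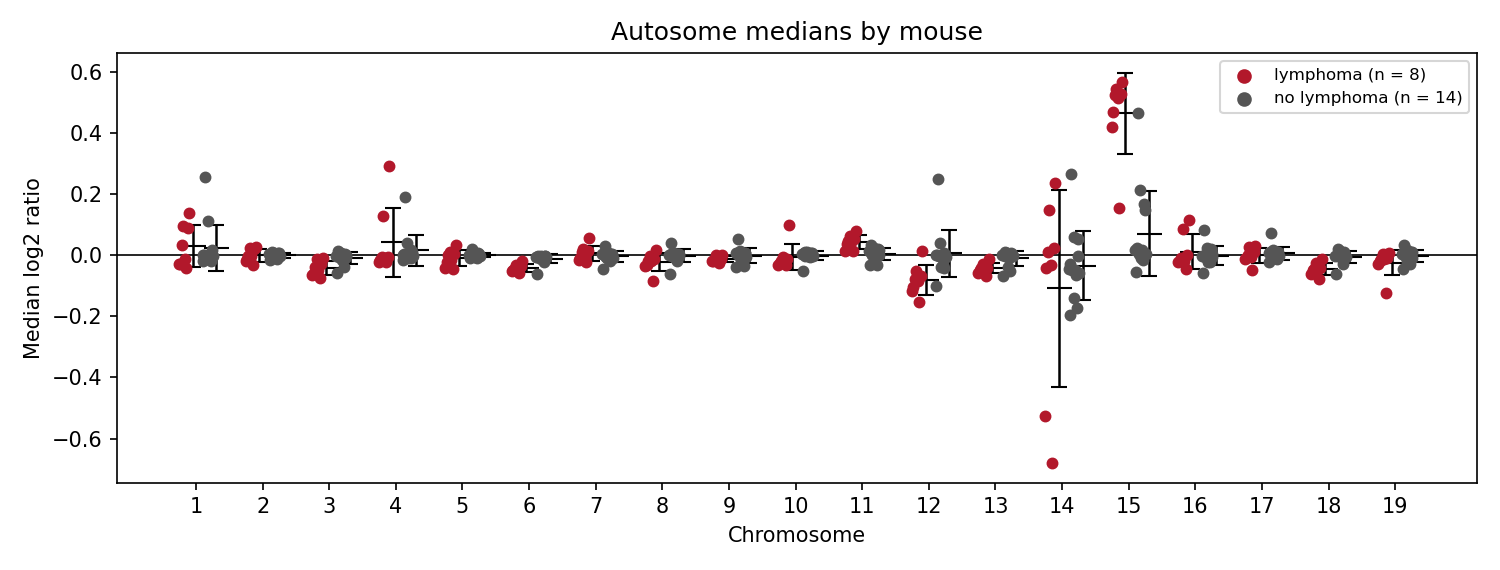
Median log2 ratio of each autosome on the y axis, with a point for each mouse, red for 8 lymphoma and grey for 14 no-lymphoma mice; bars are mean ± SD. Chromosome 15 stands out at a mean of 0.46 in lymphoma mice, and chromosome 14 has the widest spread.

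Among single genes the highest values lay on chromosome 14, before the T-cell receptor alpha locus. Gnpnat1, an enzyme of amino sugar synthesis, stood at 2.79 ± 0.45 in lymphoma mice and 0.25 ± 0.995 in the others (difference 2.53, limma adjusted p = 4.14e-05), with 8 of 8 lymphoma mice above 0. Arhgef40, Cnih1, a cargo receptor of the endoplasmic reticulum, Rnase4, a secreted ribonuclease, and Exoc5, a subunit of the exocyst, stood at 1.91, 1.85, 1.75 and 1.64 against 0.20, 0.16, 0.19 and 0.14, each above 0 in 8 of 8 lymphoma mice (limma adjusted p between 1.32e-05 and 0.000198). Armh4 and 4930503E14Rik differed by 1.53 and 1.36, and the other 3 of the 10 highest carry names that are only accessions. Each of the genes named here except 4930503E14Rik was called gained in 8 lymphoma and 3 or 4 no-lymphoma mice, and called lost in 1 no-lymphoma mouse. From 40 to 47 Mb, a stretch chosen after the profiles were seen, only the array labelled no-lymphoma mouse 1 lay below -0.25, at -0.45, and its Atm probe was also of opposite sign. The lowest values lay on distal chromosome 12. Zfp386, a zinc finger gene, Degs2, an enzyme of sphingolipid synthesis, and Ncapg2, a condensin subunit, differed by -0.80, -0.77 and -0.75 (limma adjusted p = 3.03e-05, 0.00366 and 2.56e-05), below 0 in 8, 7 and 8 of 8 lymphoma mice.

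By limma 1193 of 12986 genes differed, 867 higher and 326 lower in lymphoma mice, in 542 windows of 1 Mb. Neighbouring genes share segments and are not independent. Chromosome 15 held 468 of the higher genes and chromosome 14 132, and chromosome 12 held 69 of the lower ones. The share of higher genes was 72.7%, and 90.8% with arrays centred on the mode (988 higher, 100 lower), which raised the difference of the median gene from 0.04 to 0.08. It was 90.9% with normexp (600 higher, 60 lower). With scan batch as a fixed term in limma 426 genes differed (374 higher, 52 lower). In batch 3, with 2 arrays of each group, limma called 623. Batches 1, 5 and 6 have 1 array in a group, so their limma counts of 0, 41 and 0 (988 and 737 unadjusted where 0) do not show whether the genes hold within a batch. With the sign turned 675 genes were higher and 238 lower for scan batch 2, and 1132 and 641 for the arrays labelled no-lymphoma mouse 3, 4 and 9. Limma called 489 without the 5 arrays of a low Atm probe.

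**Figure D4:**
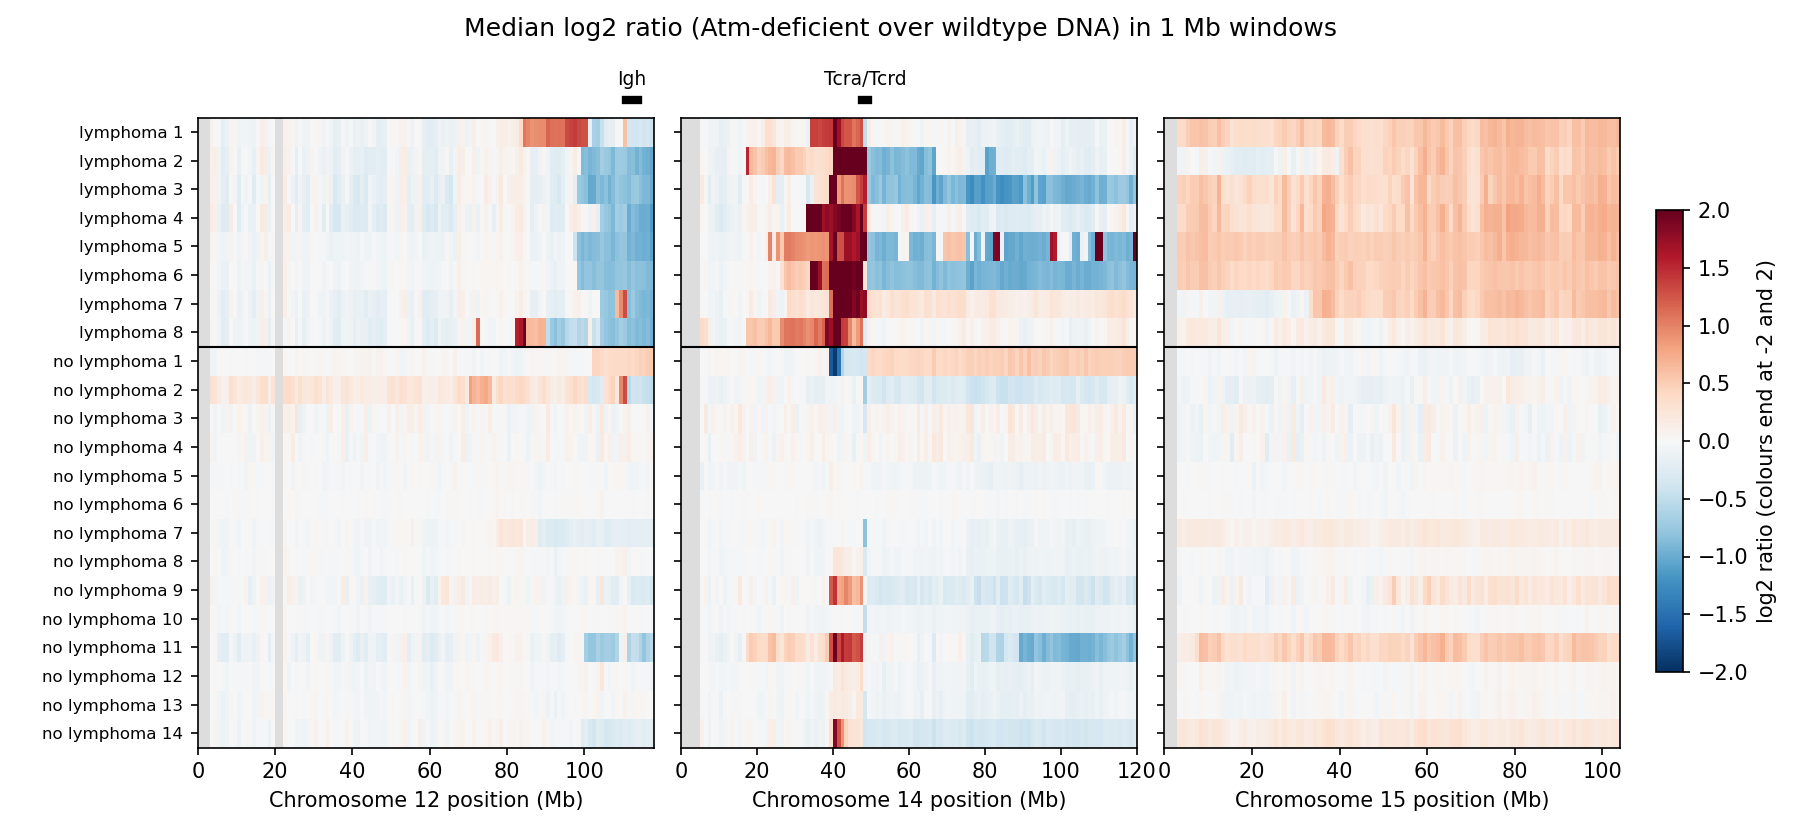
Median log2 ratio in 1 Mb windows along chromosomes 12, 14 and 15 (x axis, Mb in the array files' coordinates) for each mouse (y axis, 8 lymphoma above the line), red for above and blue for below the wildtype level, with black bars over receptor loci. All 8 lymphoma mice are red before Tcra/Tcrd on chromosome 14 and blue at the end of chromosome 12; the array labelled no-lymphoma mouse 1 shows both with opposite colours.

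Counted by mouse with a two-sided Fisher exact test, chromosomes 12, 14 and 15 stood out. On chromosome 14 27 genes between 34306101 and 39743379 were gained more often in lymphoma mice, 4930503E14Rik in 8 of 8 against 2 of 14 (Fisher exact p = 0.000141, adjusted p = 0.0234). On chromosome 15 691 genes were gained more often, among them Xrcc6, whose product binds broken DNA ends, in 7 of 8 against 1 of 14 mice (Fisher exact p = 0.000353, adjusted p = 0.0234). On chromosome 12 58 genes were lost more often, among them the kinase gene Akt1 in 6 of 8 against 0 of 14 (adjusted Fisher exact p = 0.0238). The other genes with the 10 smallest p are cDNA clones, predicted genes and names that are only accessions. Examples are 5730410E15Rik and 1110038F14Rik on chromosome 15 and A530016L24Rik, lost in 6 of 8 against 0 of 14, on chromosome 12. Those on chromosome 15 have the same p as Xrcc6, and ties were taken in alphabetical order, so the choice among tied genes is no ranking. In all, 776 calls passed, 718 gains and 58 losses, all more frequent in lymphoma mice, and 1479 passed unadjusted. The adjusted count fell to 0 when arrays were left out. By the Fisher exact test 0 passed without scan batch 2, without the 5 arrays of a low Atm probe, or without the noisiest array of each group. At an unadjusted Fisher exact p under 0.05 there were 1428, 1388 and 1453. Fewer arrays raise the p of an unchanged pattern of calls, so these counts of 0 do not show that the calls rest on particular mice. A Fisher test stratified by scan batch gave 0 (1098 unadjusted), but 288 arrangements allow no p under 0.00347, which passes over so many genes only where very many share it, so that 0 says little. The smallest p found was 0.00694. Turned signs left 716 for scan batch 2 and 904 for the arrays labelled no-lymphoma mouse 3, 4 and 9.

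Against the wildtype DNA, lymphoma mice showed 1206 genes above and 240 below 0 (limma adjusted p under 0.05, mean beyond 0.25). The highest were on chromosome 14, with Psmc6, a proteasome subunit, at 2.84 ± 0.48, Sall2, a zinc finger factor, at 1.96 ± 0.52, Cnih1 at 1.85 ± 0.68, Rnase4 at 1.75 ± 0.52, Ktn1, a kinesin-binding membrane protein, at 1.74 ± 0.42, and Armh4 at 1.67 ± 0.70. The lowest were on chromosome 12, with Cdca7l at -0.93 ± 0.22, Zfp386 at -0.82 ± 0.19 and Ptprn2, a phosphatase-like protein of secretory granules, at -0.81 ± 0.21. In mice without a tumour 8 genes lay above and 6 below 0. Above were Calr4, Slc9a3r2, Rspo1, Cep19, Adra2b, Actr1a, Hsf1 and Serpinc1, between 0.25 and 0.33. Below were Rnf126, Ccdc186, Abraxas1, Mzf1, Flg2 and Vmn2r26, between -0.31 and -0.25. Of these, Slc9a3r2, an adaptor of membrane transporters, was above 0 in 14 of 14 mice (0.30 ± 0.19, limma adjusted p = 0.00107), as were Rspo1, Cep19 and Serpinc1. Abraxas1, a partner of the break repair protein Brca1, was below 0 in 14 of 14 (-0.28 ± 0.19, limma adjusted p = 0.00248). In lymphoma mice the 8 genes above stood at 0.27, 0.34, 0.14, 0.31, 0.27, 0.29, 0.58 and 0.23 in the same order. Calr4 and Rspo1 did not pass against 0 there (limma adjusted p = 0.0781 and 0.25), nor did Serpinc1, whose mean lay within 0.25. The 6 below stood there at 0.03, -0.13, -0.04, -0.01, -0.22 and 0.02, and none passed against 0. Only Flg2 had an adjusted p under 0.05 (limma adjusted p = 0.0178), with a mean within 0.25 of 0. Between the groups Hsf1 and Vmn2r26 differed (limma adjusted p = 0.0304 and 0.0248). The counts of mice without a tumour moved when signs were turned, to 7 above and 1 below for scan batch 2 and 111 and 8 for the arrays labelled no-lymphoma mouse 3, 4 and 9. No-lymphoma mouse 9 read 1.69 at the Atm probe, the direction of most arrays, so turning its sign is no correction of dyes. Under the random block they were 4 and 2 in mice without a tumour and 1042 and 191 in lymphoma mice. With normexp limma called none in mice without a tumour, so all 14 calls ended. Within batches, where a group has at least 2 arrays, limma called 0 genes in mice without a tumour in batches 3 and 5, and 500, 1024 and 0 in lymphoma mice in batches 1, 3 and 6.

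The antigen receptor loci lose DNA when they are rearranged, Tcra/Tcrd, Tcrb and Tcrg in T cells and Igh and Igk in B cells, so both kinds were examined. The Tcra/Tcrd locus (chromosome 14, 47658042 to 49106106, between Sall2 and Dad1) was higher in lymphoma mice, at 1.16 ± 0.83 against -0.20 ± 0.29 (difference 1.36, exact permutation p = 9.38e-05, adjusted p = 0.000235), above 0 in 7 of 8. The Igh locus (chromosome 12, 110713547 to 113811274, between Tmem121 and Vipr2) was lower, at -0.72 ± 0.21 against -0.12 ± 0.24 (difference -0.60, exact permutation p = 3.13e-05, adjusted p = 0.000156), below 0 in 8 of 8. Both 1 Mb flanks together averaged -0.59 ± 0.42 against -0.01 ± 0.21 at Igh and 0.48 ± 0.29 against 0.04 ± 0.16 at Tcra/Tcrd, where the sides differed. In stretches chosen after the profiles were seen, chromosome 14 stood at 1.70 ± 0.48 against 0.19 ± 0.45 before that locus and at -0.37 ± 0.50 against -0.05 ± 0.17 beyond it. Tcrb (chromosome 6, 40815410 to 41541122) stood at -0.43 ± 0.81 and -0.23 ± 0.33 (adjusted permutation p = 0.54), Tcrg (chromosome 13, 18518097 to 18733223) at -0.18 ± 0.31 and -0.12 ± 0.25 (adjusted permutation p = 0.662), and Igk (chromosome 6, 67516358 to 70784020) at -0.11 ± 0.06 and -0.06 ± 0.08 (adjusted permutation p = 0.276). The lowest runs of 5 probes, in lymphoma mice and the others, were -4.70 and -3.74 in Tcra/Tcrd, -4.59 and -1.37 in Tcrb and -2.79 and -4.57 in Igh.

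Blocked by scan batch, Tcra/Tcrd differed by 1.45 and Igh by -0.50 (adjusted permutation p = 0.0174 for both), and within batches 1, 3, 5 and 6 by 1.82, 2.01, 0.27 and 1.53 and by -0.02, -0.74, -0.47 and -0.70. Igk passed with the block (-0.10, adjusted permutation p = 0.0174), and with the sign turned for scan batch 2 (-0.09, adjusted permutation p = 0.0464) or for the arrays labelled no-lymphoma mouse 3, 4 and 9 (-0.12, adjusted permutation p = 0.0117). The turned signs gave Tcra/Tcrd differences of 1.28 and 1.35 and Igh differences of -0.53 and -0.62.

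**Figure D5:**
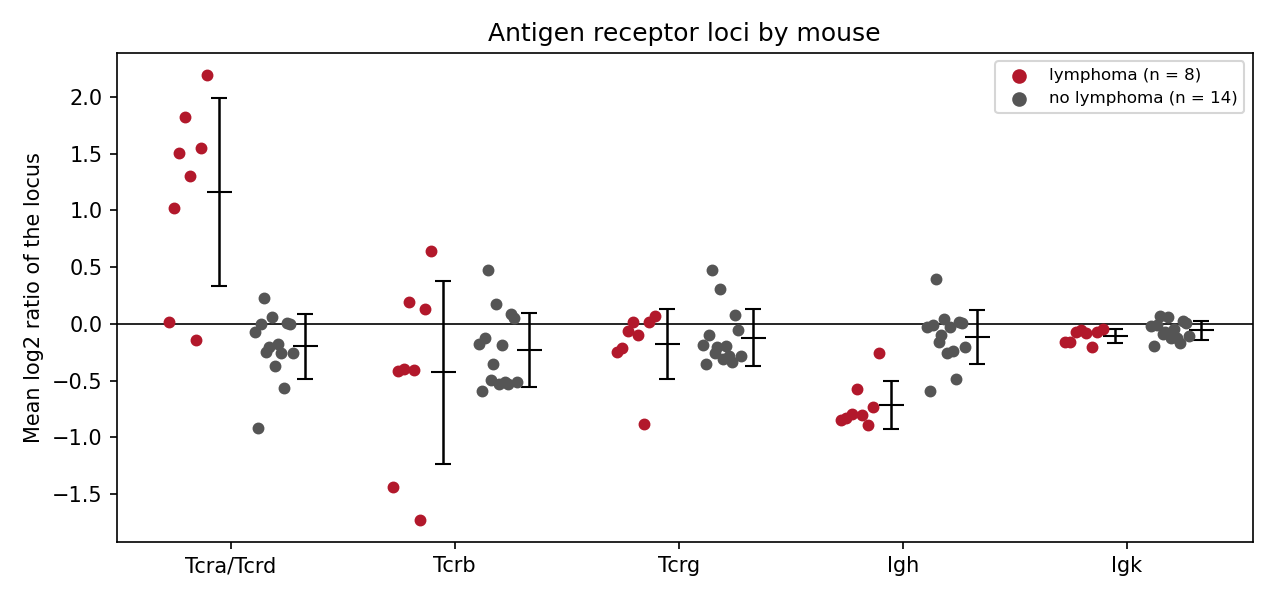
Mean log2 ratio of 5 antigen receptor loci on the y axis, with a point for each mouse, red for 8 lymphoma and grey for 14 no-lymphoma mice; bars are mean ± SD. Tcra/Tcrd averages 1.16 in lymphoma mice and Igh -0.72, while the groups overlap at Tcrb, Tcrg and Igk.

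Of 16 oncogenes measured with at least 3 probes, Il7r, the interleukin receptor of early T cells, was higher in lymphoma mice (0.50 ± 0.28 against 0.10 ± 0.21, limma adjusted p = 0.0121, above 0 in 8 of 8), as was Notch1 (0.75 ± 0.80 against 0.06 ± 0.27, limma adjusted p = 0.0462, above 0 in 8 of 8). Adjusted over the list alone 4 passed, with Abl1 and Myb added. Il7r lies on chromosome 15, as does Myc, which has 1 probe and was called gained in 7 lymphoma and 2 no-lymphoma mice (adjusted Fisher exact p = 0.0736). Notch1 did not pass with scan batch as a block (0.41, limma adjusted p = 0.496), without scan batch 2 (0.63, limma adjusted p = 0.15) or after removal of the GC trend (0.66, limma adjusted p = 0.0639), and Il7r did not pass with the block (0.33, limma adjusted p = 0.191). Over all genes Abl1, at 0.26 ± 0.24 in lymphoma mice, did not pass between groups (limma adjusted p = 0.0605), nor did Jak1, at 0.24 ± 0.23 (limma adjusted p = 0.183). Of 13 Notch pathway genes only Notch1 passed, and none adjusted over the list alone. Ncstn and Psen2, a further gamma-secretase gene, were called gained in 5 lymphoma and 2 no-lymphoma mice each, and Nrarp, a Notch inhibitor with 1 probe, in 2 and 1.

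Of 19 tumour suppressors, Bcl11b, which commits cells to the T lineage, was lower (-0.61 ± 0.20 against -0.08 ± 0.26, limma adjusted p = 0.00112), below 0 in 8 of 8 lymphoma mice and called lost in 7, against 4 no-lymphoma mice (adjusted Fisher exact p = 0.816). Adjusted over the list alone Bcl11b was lower and Tcf7 higher. Rb1 was called lost in 2 and gained in 1 mice of either group, and Gata3 gained in 2 lymphoma and 1 no-lymphoma mice, without passing between groups. Of 18 break repair genes Xrcc6 rose (0.64 ± 0.21 against 0.18 ± 0.20, limma adjusted p = 0.0008) and Xrcc4, which joins broken ends, fell (-0.14 ± 0.08 against -0.03 ± 0.05, limma adjusted p = 0.0262, below 0 in 8 of 8), also adjusted over the list alone. Xrcc4 did not pass centred on the mode (-0.08, limma adjusted p = 0.131) and Xrcc6 not with the block (0.41, limma adjusted p = 0.0719). Parp1 was called gained in 5 and Dclre1c in 2 lymphoma mice, against 2 and 0 no-lymphoma mice. Of 9 T-cell identity genes none passed by limma, over all genes or adjusted over the list alone. Cd247 and Lck were called gained in 4 and 3 lymphoma mice, against 2 and 1 no-lymphoma mice. Of 95 genes of families that vary between strains, 5 were higher, namely Olfr736, Olfr745, Sult4a1, H2-Bl and Vmn2r26, and 2 lower, namely Olfr891 and Vmn2r57. Adjusted over the list alone 5 were higher and 0 lower.

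As whole lists, T-cell identity genes differed by 0.15 (0.21 ± 0.08 against 0.06 ± 0.12), oncogenes by 0.12 (0.13 ± 0.11 against 0.01 ± 0.11), Notch pathway genes by 0.11 (0.14 ± 0.09 against 0.03 ± 0.10) and break repair genes by 0.09 (0.12 ± 0.06 against 0.04 ± 0.08), with adjusted permutation p of 0.0377, 0.0398, 0.0377 and 0.0377. Tumour suppressors differed by 0.05 (adjusted permutation p = 0.221) and strain-variable families by 0.01 (adjusted permutation p = 0.86), the latter with a median member difference of -0.03. The mean of all 12986 genes was itself higher in lymphoma mice, by 0.06 (0.07 ± 0.03 against 0.00 ± 0.05, exact permutation p = 0.00369). Less that mean no list passed (adjusted permutation p between 0.113 and 0.449). No list passed with scan batch as a block (adjusted permutation p between 0.621 and 0.767), where these 4 lists differed by 0.11, 0.04, 0.05 and 0.03. Within batches 1, 3, 5 and 6 T-cell identity genes differed by -0.05, 0.25, 0.25 and -0.07 and oncogenes by 0.00, 0.12, 0.01 and -0.00. Notch pathway genes differed by -0.01, 0.12, 0.14 and -0.10 and break repair genes by -0.05, 0.15, -0.09 and 0.08. Turning the sign left 1 list for scan batch 2 and 2 for the arrays labelled no-lymphoma mouse 3, 4 and 9.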

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

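All tests weighed here were chosen after the result was seen, except the test of the GC trend, whose reading was changed after the result was seen. The 9 outlying values come from 66 quantities examined in the 8 lymphoma mice, where chance marks about 1 in 20 groups.

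Single lymphoma mice lay far from the other 7 in 9 quantities, by the gap to the nearest mouse as a share of the whole range. Lymphoma mouse 8 had a chromosome 10 median of 0.10 against -0.01 for the next (gap 0.796), and a chromosome 15 median of 0.15 against 0.42 (gap 0.641). Lymphoma mouse 4 had 232 Mb of losses against 110 Mb (gap 0.555), and a chromosome 19 median of -0.12 against -0.03 (gap 0.728). Lymphoma mouse 2 had a Tcrg mean of -0.88 against -0.25 (gap 0.667). Lymphoma mouse 1 lost less at Bcl11b, -0.13 against -0.61 (gap 0.694), and at Zfp386, -0.37 against -0.82 (gap 0.695). Lymphoma mouse 6 was low at Lck, -0.44 against 0.17 (gap 0.607), and at the single probe of Myc, -1.25 against 0.71 (gap 0.634), although a gain was called over it in 7 lymphoma mice, this one included.

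The 3 arrays of scan batch 2 read below 0 at the Atm probe that was above 0.5 in 17 arrays. Each lay at least 3.28 noise SD from the median of the other arrays, all on the same side. The probe and the arrays were picked for these values, so the distance is no separate test of chance noise at the probe. Dyes opposite to the labels may account for the readings below 0. However, over 44 probes with a shared offset in the other arrays the correlations with their median were -0.145, -0.445 and -0.384. Since lymphoma mouse 1 and no-lymphoma mouse 9, whose Atm probe is above 0.5, came as low as -0.11 and -0.09, and the highest of the 3 lay between the limits set for either reading, this leaves opposite dyes undecided. Among no-lymphoma arrays only these 3 had a Tcrg mean above 0, at 0.08, 0.47 and 0.31 for mouse 1, 3 and 4. The same held for the chromosome 14 median, at 0.27, 0.06 and 0.05. At Tcrb they read 0.47, 0.08 and 0.05, where of the other no-lymphoma arrays mouse 2 alone was above 0, at 0.17. Lymphoma mice lay on both sides of 0 in each of these quantities, which were picked after their values were seen and not tested. The array labelled no-lymphoma mouse 1 also read -0.45 where all 8 lymphomas were gained before Tcra/Tcrd and 0.49 where all were lost on distal chromosome 12. A different strain or Atm allele in the mice of scan batch 2 was not tested.

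Several arrays labelled no lymphoma carried changes of the lymphomas. The chromosome 14 stretch from 40 to 47 Mb, chosen after the profiles were seen, stood at 1.14 to 2.39 in the 8 lymphoma mice and at 1.41, 0.83 and 0.49 in the arrays labelled no-lymphoma mouse 11, 9 and 14, and the end of chromosome 12 at -0.67, -0.44 and -0.29 in no-lymphoma mice 11, 2 and 9. Each change in these arrays lay at least 11.5 standard errors from 0, from the array's noise and the number of probes. The arrays were picked for values beyond 0.25 over 769 or 428 probes, which alone lie many standard errors out. The distance is thus no separate test of noise. The values are larger than independent noise of single probes gives over so many probes, while noise shared by neighbouring probes was not tested. A wrong or exchanged label stays open, as 0 arrays labelled lymphoma lacked both changes but these were chosen because all 8 carry them. Also open is a tumour too small to be seen or a share of tumour cells in the thymus, which is a hypothesis with no test here.

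Of the gene lists 4 of 6 were higher in lymphoma mice by 0.09 to 0.15. A shift of all tested genes could account for a part of this. Less the mean of all genes 0 of the 4 passed, with differences of 0.02 to 0.08 left. T-cell identity genes kept 0.08 of 0.15, oncogenes 0.05 of 0.12, Notch pathway genes 0.05 of 0.11 and break repair genes 0.02 of 0.09. The lost passing tests thus do not show that the shift accounts for the whole of each difference. That mean also includes the gained genes of chromosomes 14 and 15. A regional GC trend stays open. Set down before the test was that 0 of the 4 passing would point to it, and 0 passed (adjusted p 0.0619 to 0.0743), but this was read as undecided after the result was seen, because 71.9% to 93.6% of each difference stayed. The differences went only from 0.09, 0.11, 0.12 and 0.15 to 0.08, 0.08, 0.10 and 0.12 with SDs of 0.06 to 0.11 in lymphoma mice.

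Other splits of the 22 arrays into 8 and 14 were counted for both tests across genes. In limma 1 of 100 splits, the real one, reached 1193 genes, and the highest other split gave 352. In the Fisher test 1 of 100 splits, the real one, reached 776 calls, and the highest other gave 0. This argues against a chance split of all arrays, but the splits do not keep scan batches, and batches 2 and 4 hold no lymphoma array. With scan batch as a block limma called 426 genes, and the stratified Fisher test, which allows no p under 0.00347, says little, so a part of scan batch in both counts stays open.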

How the results depend on the processing

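Alternatives with a sign turned, with scan batch 2 or the 5 arrays of a low Atm probe left out, batch as a block for Atm, segments, chromosomes, loci, lists and Fisher calls, and normexp, the value table, probes well above background, mode centring or no noisiest arrays for Fisher calls were chosen after seeing the data. The cause was not tested for any change given here. The difference in altered DNA kept its direction and stayed under 0.05 in all 15 tested alternatives (148 to 484 Mb), and was 78.4 and 39.1 Mb within scan batches 1 and 5. Tcra/Tcrd and Igh passed in all 10 alternatives. Segments missed with scan batch 2 left out (39.8, exact permutation p = 0.0535), the 5 arrays left out (32.8, exact permutation p = 0.130) and the block (19.2, exact permutation p = 0.465), as did Atm with the 5 arrays left out (0.0693) and the block (0.0792). The 7 autosomes became 2 centred on the mode, where chromosome 6 (0.00086) and chromosome 13 (0.000387) reversed, and 0 with the block, where the smallest possible p adjusts to 0.066 for a chromosome on its own. The 1193 limma genes became 660 with normexp, 2549 with array weights, 710 without scan batch 2, 489 without the 5 arrays, 426 with the block and 0, 623, 41 and 0 within batches 1, 3, 5 and 6. The 14 genes off 0 without lymphoma became 0 with normexp, 8 with scan batch 2 turned, 119 with no-lymphoma mice 3, 4 and 9 turned, 301 with genes of 1 probe, 26 without the 5 arrays, 6 with the block and 9, 0, 0 and 0 within these batches. The 1446 genes off 0 in lymphoma became 3175 with genes of 1 probe and 500, 56 and 0 within batches 1, 5 and 6. Batches 1 and 6 hold 1 no-lymphoma array and batch 5 holds 1 lymphoma array, so counts that rest on these arms do not show whether genes hold within a batch. Without the noisiest array of each group 2 genes lay above and 3 below 0 in mice without a tumour, in place of 8 and 6. The 776 Fisher calls became 407 at a threshold of 0.15, 399 with normexp and 0 without scan batch 2, the 5 arrays or the noisiest arrays (1428, 1388 and 1453 unadjusted). Fewer arrays raise the p of the same calls, so these counts of 0 do not show dependence on particular mice. The Fisher calls also became 0 with the block (1098 unadjusted), which says little, since the block allows no p under 0.00347. The 4 gene lists became 0 after GC removal, without scan batch 2, without the 5 arrays and with the block, 1 with scan batch 2 turned and 2 with mice 3, 4 and 9 turned. Among single genes, chromosomes, loci, lists and parts of the measures per mouse 581 values stayed the same, 70 lost and 17 gained a passing test and 2 reversed. Of these, 378 belong to 27 named genes, where 347 stayed, 21 lost and 10 gained it. No paired analysis was possible because the labels give no number shared between the groups. Signal over background limited few spots, at most 1.54% per array.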

Other observations

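The tests and regions named here were chosen after their values were seen, and no test of a group was added.

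Notch1 stood above the other list genes of chromosome 2 in lymphoma mice 1 and 3. Dclre1c, Gata3, Nrarp and Abl1 read 0.56, 0.61, 1.32 and 0.10 in the former and -0.05, 0.28, 0.53 and 0.43 in the latter, while lymphoma mouse 2 read 0.89, 0.88, 0.74 and 0.75 there, a broad gain. In lymphoma mouse 1 the 5 probes from 26466605 to 26501946 read 1.93 to 2.11 and the next, at 26508889, 0.25. The mean over Notch1 was 1.75 in lymphoma mouse 1, 2.20 in lymphoma mouse 3 and 0.89 in lymphoma mouse 2, while the other 5 lymphoma mice lay between 0.08 and 0.32 and no-lymphoma mice 2 and 11 at 0.49 and 0.67, the latter with 0.63 at Gata3 and 0.42 at Abl1.

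The stretches beside the receptor loci differed in form between tumours. Beyond Tcra/Tcrd, from 50 to 60 Mb on chromosome 14, lymphoma mice 2, 3, 5 and 6 read -0.87, -0.83, -0.79 and -0.83, lymphoma mice 1, 4 and 8 0.04, 0.04 and 0.01, and lymphoma mouse 7 0.28, while all 8 were gained before the locus. Distal chromosome 1, a stretch chosen after the profiles were seen, read 0.46 to 0.55 in lymphoma mice 3, 4, 5, 6 and 8 and -0.01 to -0.04 in the other 3. Akt1, beside Igh, read -0.64 to -0.74 in 6 lymphoma mice, but 0.69 and 1.26 in lymphoma mice 1 and 7, as well as 1.34 in no-lymphoma mouse 2. Tcrb ran from -1.73 in lymphoma mouse 2 and -1.44 in lymphoma mouse 5 to 0.64 in lymphoma mouse 3.

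The sex chromosomes entered no comparison. The X median was -1.05 and -1.08 in lymphoma mice 1 and 4 and 0.93 in no-lymphoma mouse 10, and the Y median was 1.43, 4.20 and -3.95 in the same 3 mice. In the other 19 arrays the X median lay between -0.41 and 0.03, and the Y median was -1.09 and -1.19 in no-lymphoma mice 5 and 6, the other arrays of a low Atm probe.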
